A study of Mus musculus with 16 samples.

How the data were processed

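RNA was measured in CD8+ T cells that had been flow-sorted from the bone marrow of mice with bone marrow failure (BMF), an immune-mediated loss of marrow cells, treated with or without baricitinib (BAR), an inhibitor of the kinases JAK1 and JAK2. Per the labels, cells were collected at day 10 and day 14 after induction, polyA RNA was made into libraries with the SMART-Seq mRNA LP kit, and sequencing was on an Illumina NovaSeq. There were 16 libraries in 4 groups: 5 BMF and 5 BAR libraries at day 10, and 3 BMF and 3 BAR libraries at day 14. The labels describe the groups partly as pooled cells, and nothing states that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Replicate numbers follow the order of deposition, pair no libraries, and serve as names. The labels give no batch, harvest date or sequencing run.

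The authors deposited a table of raw read counts per gene symbol, whole numbers that had not been normalised. Reads had been aligned to the mouse build mm10 with HISAT2 2.0.5, per the submitters' processing notes; the counting tool, the annotation behind the counts and the use of strand are not given in the sources used here. Without strand information, reads from overlapping or antisense genes cannot be told apart. Near-identical copies (Gbp6 and Gbp10, Hspa1a and Hspa1b) could have shared reads, so values of these genes are uncertain. Related genes that are less alike (Serpinb9 and Serpinb9b, Gzmb and Gzmc, Phf11b and its neighbours) could have shared some reads, to an extent that was not tested. The deposited count table had 24421 gene entries. Of these, 27 carried calendar dates in place of symbols, which hid the gene, and were left out; they held 0.234% to 0.293% of a library's counts. All sample columns were used, and 24394 genes remained. Totals per library ran from 26134894 to 58823116 counts. The 26 pairs of libraries within groups differed by far more than sampling noise, with a chi-square of 11.2 to 347 per degree of freedom over genes with at least 20 counts, so no library was counted as a copy of another.

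Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with edgeR's filter by group, which left 14862 genes, and library sizes were scaled by TMM, which corrects for differences in composition. A quasi-likelihood model with robust dispersions was fitted to all 16 libraries with a mean per group and no covariate. Its common biological coefficient of variation was 0.198. F-tests compared BAR with BMF at each day, the BAR effect between days, and day 14 with day 10 within each arm; p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Every adjusted p for a gene is from this edgeR test unless stated otherwise. The standard error (SE) of a log2 fold change was its size divided by the square root of its F value. Levels are CPM (counts scaled to a common library total) given as mean ± SD; log2 CPM used a prior count of 2. Gene positions were taken by symbol from the GENCODE vM21 annotation of GRCm38 (mm10).

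There were 19 functional gene lists and 13 lists of markers of other cell types. The functional lists were type I interferon-stimulated genes, interferon-gamma-induced genes, STAT5 and common gamma chain cytokine targets, JAK-STAT pathway components, cytotoxic effector molecules, effector differentiation, naive and memory markers, exhaustion and inhibitory receptors, T cell receptor signalling and CD8 T cell identity, DNA replication and G1/S genes, G2/M and mitosis genes, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, MYC and ribosome biogenesis genes, the unfolded protein and amino acid stress response, homing and chemokine receptors, apoptosis regulators and p53 targets, and immediate early and dissociation stress genes. Functional lists were tested against the other genes with camera at a preset correlation of 0.01, adjusted over the 19 lists, and again with an estimated correlation; fry, which asks whether a list's genes move on balance in either direction by themselves, was run beside it (limma 3.58.1). Members were counted by the gene test, adjusted over all genes and adjusted over the list alone. The marker lists covered erythroid cells, neutrophils and their precursors, monocytes and macrophages, dendritic cells, B cells and plasma cells, CD4 and regulatory T cells, natural killer cells, gamma delta T cells, megakaryocytes and platelets, stem and progenitor cells, stroma and endothelium, mast cells with basophils and eosinophils, and sex-linked genes. Their CPM were summed per library and compared by an exact two-sided permutation test, adjusted over the 13 lists. With 5 against 5 libraries the smallest p this test can give is 0.00794, and with 3 against 3 it is 0.1, so no marker sum could pass the threshold at day 14.

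Genes named in the text followed a fixed rule. For BAR against BMF at each day it took the 8 largest rises and 8 largest falls past the threshold, with a mean of at least 10 CPM in an arm and no overlap of CPM between the arms, leaving out predicted genes and variable segments of antigen receptors. It added up to 3 members of each functional list with the smallest adjusted p, and 16 genes of JAK-STAT signalling and T cell function in every case. For the other comparisons it took the 5 largest changes in each direction. Marker genes are named as members of their lists. A few genes that the rule took are not reported here; they remain in the counts. The comparisons, tests, lists, naming rule and main alternatives were fixed before the data were examined.

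The edgeR steps were tested on counts simulated for the 14862 genes from the measured means and library sizes, with 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold. For the day 10 comparison 55.2%, 71.6% and 80.3% of them were recovered, and 2.82% of calls were false. For day 14 the shares were 34.3%, 67.2% and 74.2%, with 4.10% false. Changes of 1.5-fold were therefore often missed in this simulation. It changed far fewer genes than were called in the data (2145 at day 10 and 3738 at day 14). Adjustment over all genes is stricter when few genes change, so these shares do not measure recovery in the data. Alternatives were DESeq2 1.42.0, limma voom with quality weights, a test against a fold of 1.5, DESeq2's size factors, no filter or a mean of at least 10 CPM, other-cell genes left out before scaling, 1 surrogate variable (sva 3.50.0), fits of only the groups compared, and leaving out each library in turn. Alternatives added after the data were seen took the level of Rn45s (the 45S precursor of ribosomal RNA) or of the neutrophil list as a covariate, left out Rn45s and Lars2, left out the 3 BMF day 10 libraries with over 4% of counts on Rn45s, or kept 2 of the 5 BMF day 10 libraries.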

Results

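Gene expression was measured in CD8+ T cells sorted from the bone marrow of mice with bone marrow failure, a model in which T cells destroy the marrow. Libraries came from mice without drug (BMF) and from mice given baricitinib (BAR), which blocks the kinases JAK1 and JAK2 that pass on signals from interferon and interleukin receptors. There were 5 libraries per arm at day 10 and 3 per arm at day 14. Depth at day 10 was 36784100 ± 9365840 counts in BMF and 48911400 ± 10088900 in BAR (SD, n = 5 each; exact two-sided permutation p = 0.0873). At day 14 it was 42243300 ± 2752200 in BMF and 41488600 ± 4145200 in BAR (SD, n = 3 each; exact p = 0.8). The first principal component, with 44.0% of the variance of the 1000 most variable genes, separated the days, and the second, with 34.4%, separated the arms at day 14. The first also divided the day 10 libraries across the arms. BMF replicates 1 to 3 and BAR replicates 2 and 3 lay between -45.6 and -29.3, and the other day 10 libraries between -12.3 and 3.88. Thinned to 26066991 counts, libraries held a count for 19415 (BMF) and 18919 (BAR) genes on average at day 10, against 15055 (BMF) and 15494 (BAR) at day 14 (all day 14 against all day 10, permutation p = 0.000125). Within day 10, BMF replicates 1 to 3 and BAR replicates 2 and 3 held 19395 to 20997 genes, and the other libraries 17261 to 19009. The labels name nothing behind this division, which is uneven between the arms, and the main fit held no term for it.

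At day 10, what baricitinib changed in marrow CD8 T cells was asked by comparing 5 BAR with 5 BMF libraries. The receptor genes Il12rb2 and Il2ra were lower with the drug, as were 14 of 28 genes of effector differentiation, and 30 of 44 type I interferon-stimulated genes were higher. Il12rb2, a subunit of the interleukin-12 receptor that drives effector differentiation, was at 22.2 ± 3.91 CPM in BMF and 4.29 ± 0.692 CPM in BAR (log2 fold change -2.37, SE 0.176, adjusted p = 5.54e-07). Il2ra, the high-affinity subunit of the interleukin-2 receptor, was at 36.4 ± 8.85 CPM in BMF and 16.3 ± 3.87 CPM in BAR (log2 -1.16, SE 0.217, adjusted p = 0.00464). Usp18, an interferon-stimulated protease, was at 39.0 ± 7.87 CPM in BMF and 72.8 ± 7.11 CPM in BAR (log2 0.90, SE 0.116, adjusted p = 0.000198). Of 14862 genes tested, edgeR called 2145, of which 965 rose and 1180 fell; 239 rose and 127 fell by at least 2-fold. Of the called genes 950 had no overlap of CPM between the arms, as had 1176 of all genes tested; for a gene with no difference the chance of this is 0.00794. The number called fell to 1036, 1263 and 1191 without BMF replicates 3, 2 and 4, and was 3615 without BMF replicate 5. It was 38 when tested against a fold of 1.5, 3611 with limma voom, 66 with Rn45s as a covariate (where 24 of the 2145 genes had the opposite sign), 111 without the 3 BMF libraries richest in Rn45s and 1356 with the neutrophil list as a covariate.

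Beside those changes, Rn45s, the precursor of ribosomal RNA, took 4.01 ± 2.004% of counts in BMF and 1.30 ± 0.102% in BAR at day 10 (SD, n = 5 each; exact two-sided p = 0.0476). Single BMF libraries held 5.53%, 4.83%, 5.81%, 2.73% and 1.15%. Counts on Lars2, by its symbol the mitochondrial leucyl-tRNA synthetase, took 3.24 ± 1.77% in BMF and 0.748 ± 0.0904% in BAR (exact p = 0.0159). Lars2 was among the largest falls (log2 -2.25, SE 0.380, edgeR adjusted p = 0.00319). Its shares in BMF replicates 1 to 5 were 3.57%, 3.50%, 5.73%, 2.54% and 0.848%, in the same order of size as Rn45s. Whether the fall is a change in expression of the synthetase itself was not tested. At day 14 Rn45s took 2.21 ± 0.443% in BMF and 1.46 ± 0.847% in BAR (n = 3 each, exact p = 0.2). When 2 of the 5 BMF day 10 libraries were kept, the 10 possible choices gave a median of 1354 genes, from 109 to 2825. The 4 choices that held BMF replicate 5 gave 109 to 146 genes, though 3 of them also held a library rich in Rn45s, and the 6 choices without it gave 1234 to 2825. The 111 genes without the Rn45s-rich libraries, where BMF replicates 4 and 5 remain, therefore go with replicate 5 as well as with Rn45s.

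Among genes with at least 10 CPM in an arm and no overlap between the arms, the largest rises at day 10 were genes of B cells and dendritic cells. Spib, a transcription factor of B cells and plasmacytoid dendritic cells (chromosome 7, 44525993 to 44532071), was at 1.42 ± 1.10 CPM in BMF and 24.8 ± 32.6 CPM in BAR (log2 4.15, SE 0.932, adjusted p = 0.0142). Cd79a, a chain of the B cell receptor complex (chromosome 7, 24897381 to 24902197), rose with a log2 fold change of 4.14 (SE 0.861, adjusted p = 0.0102). Fcrla (log2 3.897), Ly6d (3.40), Cox6a2 (3.38), Mzb1 (2.92) and Atp1b1 (2.73) rose with adjusted p between 0.0115 and 0.0159. A single library, BAR replicate 3, held 82.9 CPM of Spib and 78.2 CPM of Cd79a against 5.27 to 13.9 CPM and 3.59 to 12.2 CPM in the other BAR libraries. The remaining large rise was Ccdc80, a secreted matrix protein (chromosome 16, 45093402 to 45128077), from 1.24 ± 0.409 to 12.7 ± 6.22 CPM (log2 3.37, SE 0.381, adjusted p = 0.000198).

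In the list of B cells and plasma cells 13 of 15 tested genes rose at day 10 and 0 fell, and the summed markers were at 203 ± 247 CPM in BAR and 24.5 ± 8.34 CPM in BMF (SD, n = 5 each; exact two-sided p = 0.00794, adjusted p = 0.0206). Erythroid markers stood at 167 ± 74.96 against 53.01 ± 42.0 CPM (exact p = 0.0238, adjusted p = 0.0442), with 8 of 13 genes higher. BMF replicate 5 held 125 CPM of these against 22.2 to 54.8 CPM in the other BMF libraries. For monocytes and macrophages 10 of 22 genes rose, and the sum was 1351 ± 495 against 787 ± 362 CPM (exact p = 0.0794). Neutrophil markers were at 10004 against 6352 CPM (exact p = 0.183; 0 of 21 genes called by edgeR) and dendritic cell markers at 1816 against 859 CPM (exact p = 0.127; 3 genes rose and 1 fell of 18). BAR replicate 3 held 641 CPM of B cell markers (48.8 to 112 in the other BAR libraries) and 4886 CPM of dendritic cell markers (943 to 1160). Stroma and endothelium markers were higher in BAR, at 189 against 115 CPM (exact p = 0.00794), and natural killer cell markers, many of which CD8 T cells also carry, were at 795 against 632 CPM (exact p = 0.0238). Lower in BAR were the markers of CD4 and regulatory T cells (392 against 462 CPM), megakaryocytes and platelets (38.5 against 65.7 CPM) and stem and progenitor cells (516 against 596 CPM), each with exact p = 0.00794. The most abundant member in BMF was Gata3 in the CD4 list, Itgb3 (60.1 CPM) in the megakaryocyte list and Ly6a (570 CPM) in the stem cell list, genes that activated T cells can also express. By mean log2 level these 3 lists stood higher in BAR, by 0.05, 0.12 and 0.49 (exact p = 0.706, 0.667 and 0.143), so their direction depends on the measure. Gamma delta T cell markers (22.3 against 25.9 CPM, exact p = 0.246), mast cell, basophil and eosinophil markers (149 against 110 CPM, exact p = 0.341) and sex-linked genes (160 against 186 CPM, exact p = 0.349) did not differ beyond the spread. By mean log2 level in place of the sum, 0 of the 13 lists passed. B cell markers were higher in BAR by 2.79 with the smallest exact p this test can give (0.00794, adjusted p = 0.0774). A list at that p cannot pass alone after adjustment over 13 lists, so this 0 does not show that the rise depends on the measure. Erythroid, monocyte and dendritic cell markers were higher by 1.72, 0.74 and 1.25 (exact p = 0.0238 each), and only sex-linked genes were lower (-0.18, exact p = 0.0873).

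**Figure D1:**
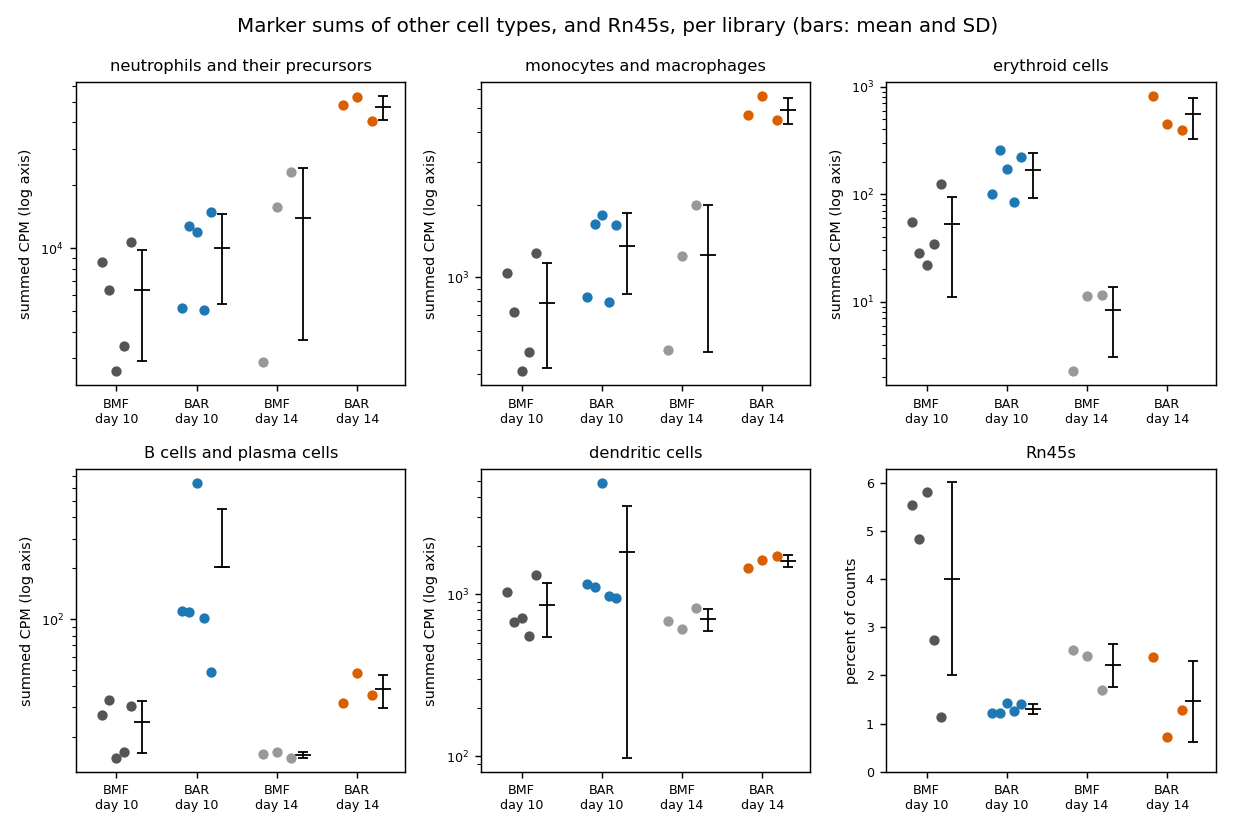
Summed CPM of 5 marker lists of other cell types (log axes) and percent of counts on Rn45s (linear axis) for each of the 16 libraries, with mean and SD at the right of each group (no lower bar where the mean minus the SD lies below 0). The 3 BAR libraries at day 14 lie above the BMF libraries for the 5 lists, and at day 10 BAR replicate 3 stands apart for B cell and dendritic cell markers.

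By the same limits on CPM and overlap, the largest falls at day 10 were Serpinb9b, a serine protease inhibitor (chromosome 13, 33027416 to 33041884), with a log2 fold change of -3.13 (SE 0.260, adjusted p = 1.99e-06), and Ermn, a cytoskeletal protein (log2 -2.57, SE 0.262, adjusted p = 5.15e-05). Serpinb9b lies close to the related gene Serpinb9, so some reads could have been shared between them. Il12rb2 (chromosome 6, 67291318 to 67376188) came next, followed by Epas1, which encodes the hypoxia-inducible factor HIF-2 alpha (28.3 ± 6.61 CPM in BMF, 5.93 ± 1.55 CPM in BAR; log2 -2.25, adjusted p = 1.66e-05). Rora, a nuclear receptor (log2 -1.80), AA467197 (-1.76) and Satb1, a chromatin organiser of T cells (-1.72, SE 0.129, adjusted p = 6.25e-07), also fell. Satb1 was at 90.8 ± 13.6 CPM in BMF and 27.6 ± 4.57 CPM in BAR.

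Among targets of STAT5 and the common gamma chain cytokines, 0 of 32 measured members rose and 9 fell at day 10, and the count was the same adjusted over the list alone. Il12rb2, Il18rap (log2 -0.76, SE 0.0962, adjusted p = 0.000165) and Ifngr1, the interferon-gamma receptor (-0.50, SE 0.0728, adjusted p = 0.000512), were the members with the smallest p. Camera called the list lower (median log2 -0.14, adjusted p = 6.54e-06, and adjusted p = 0.0188 with an estimated correlation). Over 23 settings the median ran from -0.22 with limma voom to -0.06 without the libraries richest in Rn45s. Rn45s took 4.01% of counts in BMF and 1.30% in BAR. Cish, a feedback inhibitor induced by STAT5, was at 21.7 ± 6.49 CPM in BMF and 13.8 ± 2.17 CPM in BAR (log2 -0.66, SE 0.193, adjusted p = 0.0349); its call was lost without any of 7 libraries, with an adjusted p of up to 0.10005 without BMF replicate 3. JAK-STAT pathway components went both ways, with 4 rises and 4 falls among 37 members (4 and 5 adjusted over the list alone, camera adjusted p = 0.684). Ptpn2 (-0.32) and Stat4 (-0.35) fell. The kinase genes themselves gave log2 values of 0.00 for Jak1 (adjusted p = 0.99996) and -0.10 for Jak2 (adjusted p = 0.442), and Stat5a (-0.19), Socs1 (-0.03) and Socs3 (-0.14) did not pass either, with adjusted p of 0.0677, 0.879 and 0.730.

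Type I interferon-stimulated genes were called higher at day 10. Of 44 measured members 30 rose and 0 fell (36 and 0 adjusted over the list alone), with a median log2 fold change of 0.53 and a camera adjusted p of 1.31e-32 (adjusted p = 0.0188 with an estimated correlation). In the same libraries Rn45s took 4.01% of counts in BMF and 1.30% in BAR. With it as a covariate 8 members rose and 0 fell (median 0.62). Erythroid markers stood at 53.01 and 167 CPM and B cell markers at 24.5 and 203 CPM. With the neutrophil covariate 31 members rose and 0 fell (median 0.51). Dhx58, a regulator of RNA sensing, went from 18.9 ± 1.74 to 32.8 ± 2.25 CPM (log2 0.79, SE 0.0865, adjusted p = 3.41e-05), and Isg20, an antiviral exonuclease, from 39.4 ± 6.96 to 68.0 ± 4.66 CPM (log2 0.79, SE 0.1002, adjusted p = 0.000180). Interferon-gamma-induced genes did not move together, with 4 rises and 3 falls among 38 members (6 and 5 adjusted over the list alone), a median of 0.00 and a camera adjusted p of 0.237. Gbp10 (log2 1.28, adjusted p = 8.33e-06) and Gbp6 (0.61, adjusted p = 0.00107), guanylate-binding proteins that resemble each other closely enough to share reads, were among those that rose.

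Camera called both effector lists lower at day 10. In the effector differentiation list 0 of 28 members rose and 14 fell, also adjusted over the list alone (median log2 -0.36, camera adjusted p = 1.15e-07, and adjusted p = 0.0307 with an estimated correlation). With Rn45s, at 4.01% of counts in BMF and 1.30% in BAR, as a covariate the median was -0.17. In the same BAR libraries B cell and erythroid markers were higher. Bhlhe40, a transcription factor of effector and resident cells, fell by 0.88 on the log2 scale (SE 0.125, adjusted p = 0.000470). Itga1, an integrin that binds collagen (-1.26), and Ahnak, a scaffold protein (-0.99), fell as well. Of the cytotoxic effector molecules 0 of 30 rose and 8 fell (0 and 11 adjusted over the list alone, median -0.12, or -0.05 with the neutrophil covariate, camera adjusted p = 0.00115, and adjusted p = 0.287 with an estimated correlation). Members that fell were Serpinb9 (-0.78) and Serpinb6b (-0.83), which protect killer cells from their own granzymes, and the granzymes Gzmc (log2 -2.16, SE 0.355, adjusted p = 0.00184) and Gzmb (-0.47, SE 0.120, adjusted p = 0.0166). Gzmb was abundant, at 1153 ± 76.2 CPM in BMF and 832 ± 153 CPM in BAR. Ifng, at 337 ± 107 and 220 ± 32.9 CPM, did not pass (log2 -0.62, adjusted p = 0.0665), nor did Prf1 (0.07, adjusted p = 0.752) or Fasl (0.17, adjusted p = 0.162). Without BMF replicate 5, Ifng, Mki67 and Pdcd1 passed, with adjusted p of 0.0363, 0.0370 and 0.0371.

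Homing and chemokine receptors had 1 rise and 7 falls among 28 members at day 10 (2 and 8 adjusted over the list alone, median log2 -0.20, camera adjusted p = 0.00997, and adjusted p = 0.334 with an estimated correlation), and the camera call was lost without BMF replicate 5 (adjusted p = 0.0738). Itgb3 (-1.08) and Cd44 (-0.45) fell. In the list of T cell receptor signalling and CD8 identity 0 of 27 rose and 5 fell (0 and 8 adjusted over the list alone, median -0.11, camera adjusted p = 0.00229, and adjusted p = 0.497 with an estimated correlation), a call lost without BAR replicate 3 (median -0.06, adjusted p = 0.0656). Thy1 (-0.61), Fyb (-0.54) and Prkcq (-0.35) fell, while Cd8a stood at 720 ± 73.4 CPM in BMF and 665 ± 86.4 CPM in BAR (log2 -0.11, edgeR adjusted p = 0.492). Naive and memory markers had 3 rises and 3 falls of 32 (3 and 4 adjusted over the list alone, camera adjusted p = 0.144), among them Lef1 (-0.64) and Dapl1 (0.91). Tcf7, which maintains memory cells, had a log2 value of -0.05 (adjusted p = 0.858). Exhaustion and inhibitory receptors had 8 rises and 3 falls of 29 (9 and 3 adjusted over the list alone, median 0.07, camera adjusted p = 0.0321, and adjusted p = 0.488 with an estimated correlation). Cd200r1 (0.80), Cd200 (0.50) and Nt5e (0.69) rose, and Pdcd1, which encodes PD-1, had a log2 value of 0.25 (adjusted p = 0.112). Its median was 0.13 with Rn45s as a covariate. The camera call of this list was lost without BMF replicate 5 (adjusted p = 0.181), BAR replicate 1 (0.108) or BAR replicate 4 (0.121). Behind all the lists of day 10 are the same libraries, where Rn45s took 4.01% of counts in BMF and 1.30% in BAR. B cell markers stood there at 24.5 and 203 CPM and erythroid markers at 53.01 and 167 CPM.

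In both cell cycle lists more genes rose than fell with BAR at day 10, though most members did not pass. DNA replication and G1/S genes had 14 rises and 0 falls of 50 (20 and 2 adjusted over the list alone, median log2 0.11, camera adjusted p = 0.000154, and adjusted p = 0.497 with an estimated correlation). Ccne2, a cyclin of S phase entry, rose by 0.58 on the log2 scale (SE 0.103, adjusted p = 0.00226), with Cdc6 (0.39) and Pold1 (0.36). G2/M and mitosis genes had 8 rises and 1 fall of 58 (12 and 2 adjusted over the list alone, median 0.09, camera adjusted p = 0.00500, and adjusted p = 0.645 with an estimated correlation), with Cenpm (0.37), Kif20a (0.42) and Pbk (0.37) among the rises. Mki67 went the other way without passing (658 ± 140 CPM in BMF, 540 ± 34.8 CPM in BAR; log2 -0.29, adjusted p = 0.139). With Rn45s as a covariate the camera adjusted p of the mitosis list was 0.475, and without the libraries richest in Rn45s it was 0.188 with the opposite sign; the replication list had 0.196 without those libraries. Its median was 0.03 without them and 0.18 with limma voom. The mitosis call was also lost without BMF replicate 1 (0.0842), BMF replicate 2 (0.0786) or BAR replicate 4 (0.0848).

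Cholesterol biosynthesis had 5 rises and 0 falls of 26 members at day 10 (6 and 0 adjusted over the list alone, median log2 0.19, camera adjusted p = 9.35e-05, and adjusted p = 0.287 with an estimated correlation; median 0.12 with Rn45s as a covariate), including Sqle, squalene epoxidase (0.43, adjusted p = 0.0156). Fdps (0.44) and Acat2 (0.33) each lost the call without any of several libraries, with adjusted p of up to 0.0829 and 0.0925 without BMF replicate 3. Glycolysis had 1 rise and 7 falls of 26 (1 and 8 adjusted over the list alone, median -0.16, camera adjusted p = 0.0116, and adjusted p = 0.497 with an estimated correlation; median -0.09 and adjusted p = 0.285 without BMF replicate 5, and median -0.24 with Rn45s as a covariate). Hk2, hexokinase 2 (-0.63), and Slc2a1, the glucose transporter GLUT1 (-0.39), fell, and Ldhb rose (1.09). Apoptosis regulators and p53 targets had 0 rises and 8 falls of 38, also adjusted over the list alone (median -0.08, camera adjusted p = 0.00221, and adjusted p = 0.0188 with an estimated correlation; adjusted p = 0.0660 among genes of at least 10 CPM; median -0.12 without the libraries richest in Rn45s). Bbc3, which encodes the cell death protein PUMA, was at 11.6 ± 1.30 CPM in BMF and 5.33 ± 0.630 CPM in BAR (log2 -1.12, SE 0.119, adjusted p = 2.73e-05), with Zmat3 (-0.96) and Cdkn1a (-0.95) also lower. Immediate early and dissociation stress genes had 1 rise and 5 falls of 33, also adjusted over the list alone (median -0.33, camera adjusted p = 0.00500, and adjusted p = 0.497 with an estimated correlation). Egr3 (-1.18), Ier5 (-1.43) and Hsp90aa1 (-1.04) fell; this camera call was lost with Rn45s as a covariate (0.863, opposite sign), without the libraries richest in Rn45s (0.888) or without BMF replicate 1 (0.201).

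Also without a camera call at day 10 were oxidative phosphorylation, MYC and ribosome biogenesis genes, and the unfolded protein and amino acid stress response. Oxidative phosphorylation had 3 rises and 0 falls of 59 (0 and 0 adjusted over the list alone, camera adjusted p = 0.504). These were Ndufs8 (0.27), Uqcrc1 (0.31) and Cyc1 (0.30), whose adjusted p rose to 0.106, 0.107 and 0.0951 without BMF replicate 3. MYC and ribosome biogenesis had 5 rises and 1 fall of 43 (6 and 2 adjusted over the list alone, camera adjusted p = 0.198), among them Srm (0.40), Ifrd2 (0.33) and Nop14 (-0.40). The stress response list had 4 rises and 2 falls of 35 (5 and 3 adjusted over the list alone, camera adjusted p = 0.133), with Hspa5, the chaperone BiP, higher (0.40) and Ddit4 (-0.81) and Atf4 (-1.05) lower.

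**Figure D2:**
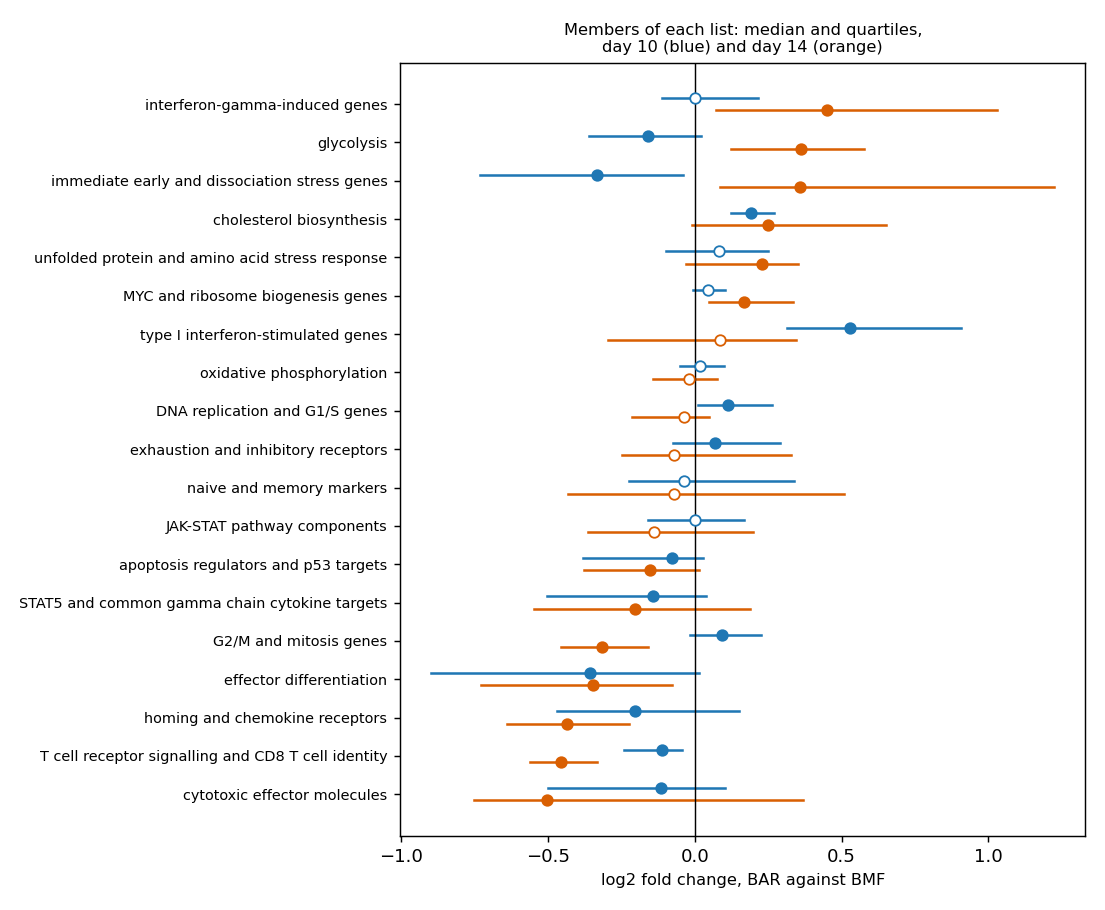
Median (points) and interquartile range (lines) of the log2 fold changes, BAR against BMF, of the members of the 19 functional lists at day 10 (blue) and day 14 (orange); filled points passed camera with the preset correlation. Type I interferon-stimulated genes have a median of 0.53 at day 10 and 0.09 at day 14, and mitosis genes of 0.09 and -0.31.

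At day 14, the same question was asked with 3 BAR and 3 BMF libraries. Genes of erythroid cells were among the largest rises. Camera called the interferon-gamma, glycolysis and cholesterol lists higher with the drug, with rises for 17 of 38, 10 of 26 and 11 of 26 members. It called the cytotoxic, T cell receptor and mitosis lists lower, with falls for 15 of 30, 21 of 27 and 29 of 58. By camera with an estimated correlation 0 of the 19 lists passed at day 14. Gzma, the granzyme A of killer cells, was at 221 ± 53.2 CPM in BMF and 36.3 ± 9.76 CPM in BAR (log2 -2.61, SE 0.264, adjusted p = 3.61e-05). Gbp2, an interferon-gamma-induced GTPase, was at 190 ± 40.8 CPM in BMF and 630 ± 81.6 CPM in BAR (log2 1.73, SE 0.191, adjusted p = 3.44e-05). Bcl2, which protects T cells from cell death, was at 169 ± 50.1 CPM in BMF and 69.3 ± 2.59 CPM in BAR (log2 -1.28, SE 0.174, adjusted p = 0.000123). Of 14862 genes edgeR called 3738, of which 1923 rose and 1815 fell; 1083 rose and 175 fell by at least 2-fold. The count was 2119, 2289 and 2153 without BMF replicate 2, BMF replicate 1 or BAR replicate 2, 993 with the neutrophil list as a covariate, 5919 with limma voom, and 556 (86.5% of them rises, against 51.4%) when tested against a fold of 1.5.

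Erythroid genes were higher in BAR at day 14, and the summed markers of several other cell types had higher means, although no sum could pass the threshold with 3 against 3 libraries. Neutrophil markers summed to 47182 ± 6220 CPM in BAR and 13918 ± 10278 CPM in BMF (SD, n = 3 each), 4.72% against 1.39% of counts, with BMF libraries from 2851 to 23164 CPM. Monocyte and macrophage markers were at 4914 against 1242 CPM and erythroid markers at 555 ± 228 against 8.40 ± 5.32 CPM. Dendritic cell markers were at 1610 against 705 CPM, mast cell, basophil and eosinophil markers at 464 against 21.3 CPM (8.79, 12.4 and 42.6 CPM in BMF replicates 1, 2 and 3), and stroma and endothelium markers at 319 against 157 CPM. B cell markers were at 38.4 against 15.7 CPM, and CD4 and regulatory T cell markers at 371 against 338 CPM. For each of these lists the arms did not overlap, and the exact two-sided p was 0.1, the smallest this design can give. Natural killer cell (708 against 671 CPM, exact p = 0.4), gamma delta T cell (21.2 against 21.6 CPM, exact p = 0.9), megakaryocyte (45.7 against 51.3 CPM, exact p = 0.5), stem and progenitor cell (332 against 384 CPM, exact p = 0.3) and sex-linked markers (60.9 against 81.5 CPM, exact p = 0.3) overlapped between the arms. By edgeR, 13 of 13 erythroid genes rose, as did 10 of 15 mast cell, basophil and eosinophil genes, 10 of 16 stem and progenitor genes and 7 of 13 megakaryocyte genes. Of the neutrophil genes 0 of 21 passed either way; S100a8 had a log2 fold change of 1.38 (SE 0.685, adjusted p = 0.161) and Ngp of 2.06 (SE 0.757, adjusted p = 0.0647). Monocyte and macrophage genes split, with 7 rises, such as Lyz2 (2.17) and F13a1 (3.46), and 7 falls, such as C1qa (-1.25) and Mrc1 (-2.04), genes of resident macrophages. The list values of day 14 that follow come from these same libraries.

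The rises past the naming rule at day 14 were led by Sphk1, sphingosine kinase 1 (chromosome 11, 116530925 to 116536674; log2 7.83, SE 0.966, adjusted p = 0.000127), Slc38a5 (7.33) and Aqp1, a water channel of red cells (chromosome 6, 55336432 to 55348555; log2 7.26, SE 0.792, adjusted p = 7.84e-05). Cldn13 (7.02), Rhag (6.91), Abcb4 (6.74) and Ermap (6.73) rose too. Levels in BMF were below 1 CPM for these 7 genes, 0.213 ± 0.208 CPM for Aqp1 against 34.2 ± 15.1 CPM in BAR, so the size of these folds rests on few counts. By the same limits on CPM and overlap, the largest falls were Gzma (chromosome 13, 113093825 to 113100981), Fabp4, a fatty acid-binding protein (log2 -2.32, SE 0.277, adjusted p = 3.98e-05), and D8Ertd82e (-1.82), which has no position by that symbol in the annotation. Prr5, a subunit of the kinase complex mTORC2 (-1.47), Il12rb2 (-1.38, SE 0.223, adjusted p = 0.000363), Cd7, a T cell surface protein (-1.34), Bcl2 (chromosome 1, 106538178 to 106714274) and Vax2 (-1.28) followed.

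Camera called interferon-gamma-induced genes higher at day 14. Of 38 members 17 rose and 2 fell (20 and 3 adjusted over the list alone), with a median log2 of 0.45 and a camera adjusted p of 6.24e-09 (adjusted p = 0.111 with an estimated correlation). Irgm2 was at 42.5 ± 4.60 CPM in BMF and 90.6 ± 12.4 CPM in BAR (log2 1.09, SE 0.117, adjusted p = 1.58e-05), and Irgm1, another GTPase of defence against intracellular microbes, rose by 0.87 on the log2 scale. Ifng itself was at 194 ± 9.31 CPM in BMF and 262 ± 91.6 CPM in BAR (log2 0.44, adjusted p = 0.267). Type I interferon-stimulated genes went both ways, with 8 rises and 9 falls of 44 (8 and 10 adjusted over the list alone, median 0.09, camera adjusted p = 0.855). Ifi44 (1.67) and Isg20 (0.91) rose, and Phf11b fell (-0.77). In the same libraries monocyte and macrophage markers were at 1242 CPM in BMF and 4914 CPM in BAR.

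STAT5 and common gamma chain targets had 5 rises and 11 falls of 32 at day 14 (6 and 13 adjusted over the list alone, median log2 -0.20, camera adjusted p = 0.0101, and adjusted p = 0.196 with an estimated correlation; adjusted p = 0.0505 among genes of at least 10 CPM; median -0.11 without BMF replicate 1). Ifngr1 fell from 533 ± 49.8 to 295 ± 12.3 CPM (log2 -0.85, SE 0.0945, adjusted p = 1.96e-05). Pim2, a survival kinase induced by STAT5 (-0.93), and Cish (36.2 ± 10.9 and 16.9 ± 0.778 CPM; log2 -1.10, SE 0.249, adjusted p = 0.00549) fell as well, while Il2ra had a log2 value of -0.27 (adjusted p = 0.531). JAK-STAT components had 7 rises and 11 falls of 37 (7 and 12 adjusted over the list alone, median -0.14, mean 0.00, camera adjusted p = 0.0954), with Ifnar1, a chain of the type I interferon receptor, lower (-0.39). Jak1 fell (log2 -0.33, SE 0.105, adjusted p = 0.0276) and Socs1 rose (0.42, SE 0.140, adjusted p = 0.0368), but each call was lost without any of 4 of the 6 libraries, with adjusted p of up to 0.117 and 0.157 without BMF replicate 2. Jak2 (-0.17, adjusted p = 0.266), Stat5a (0.07, adjusted p = 0.588) and Socs3 (0.33, adjusted p = 0.451) did not pass.

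**Figure D3:**
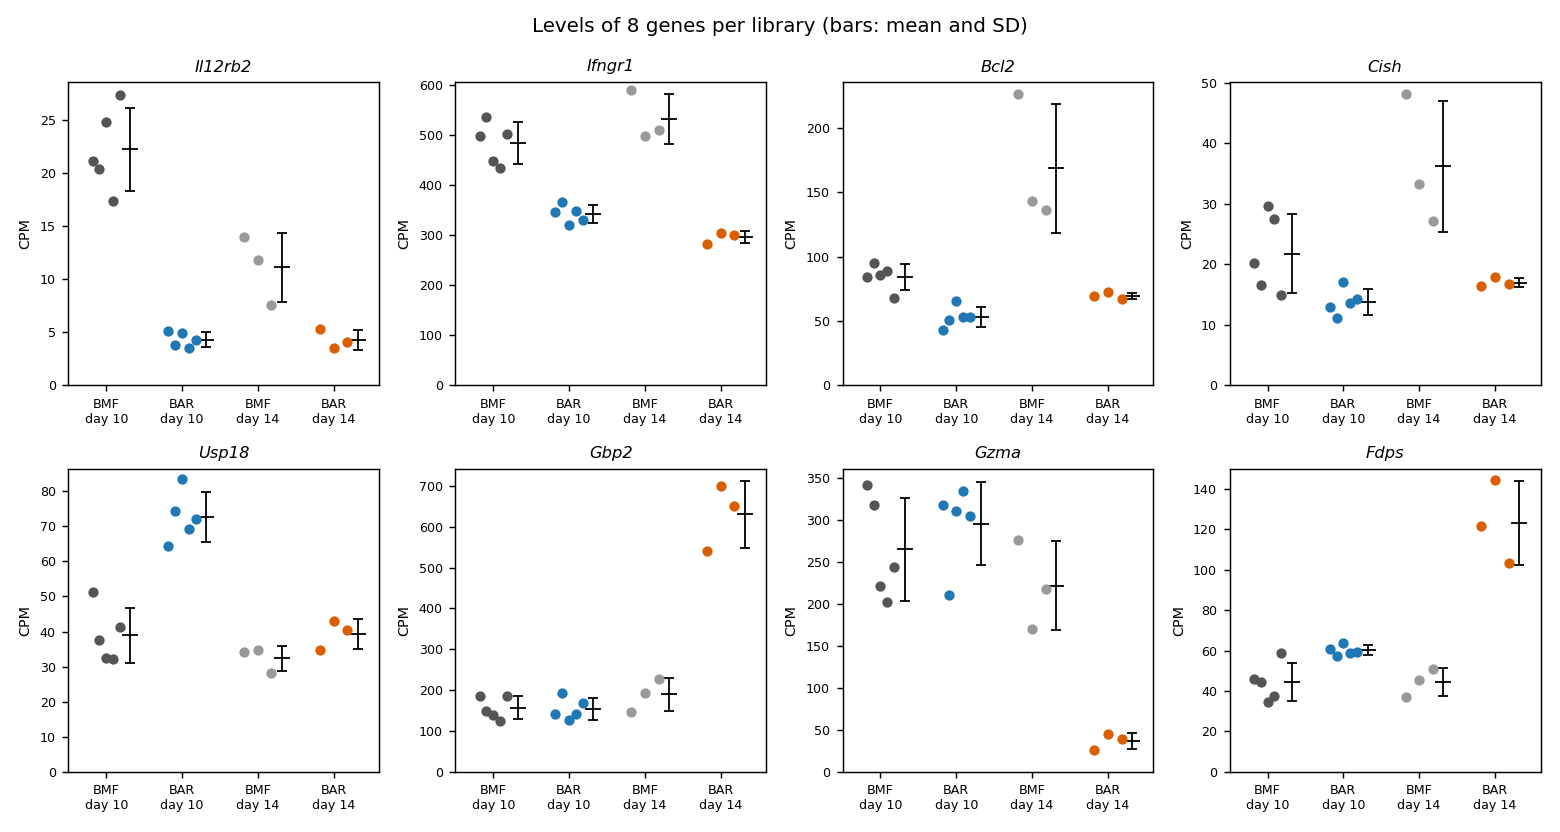
CPM of 8 genes in each of the 16 libraries (points) with mean and SD per group. Il12rb2, Ifngr1, Bcl2 and Cish have lower means in BAR than in BMF at both days, Usp18 is higher at day 10, and Gbp2, Fdps (higher in BAR) and Gzma (lower in BAR) differ most at day 14.

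Cytotoxic effector molecules had 4 rises and 15 falls of 30 at day 14 (5 and 16 adjusted over the list alone, median log2 -0.50, or -0.26 with the neutrophil covariate, camera adjusted p = 0.00155, and adjusted p = 0.260 with an estimated correlation). Gzmb fell from 622 ± 65.5 to 411 ± 71.7 CPM (log2 -0.60, SE 0.155, adjusted p = 0.00973), Fasl by 0.52 on the log2 scale (SE 0.106, adjusted p = 0.00196), and Serpinb6b (-0.80) and Serpinb9 (-0.73) again fell, as at day 10. Prf1, perforin, was at 521 ± 107 and 704 ± 20.1 CPM (log2 0.43, adjusted p = 0.0793, and 0.0171 without BMF replicate 3). Effector differentiation had 2 rises and 12 falls of 28 (4 and 13 adjusted over the list alone, median -0.35, or -0.54 without BAR replicate 1, camera adjusted p = 0.00155, and adjusted p = 0.196 with an estimated correlation). Runx3, which sets the CD8 lineage and effector program (-0.69), Id2 (-0.93) and Ahnak (-1.05) fell. Homing and chemokine receptors had 4 rises and 11 falls of 28 (4 and 15 adjusted over the list alone, median -0.43, camera adjusted p = 0.00175, and adjusted p = 0.196 with an estimated correlation), with Cxcr3, a receptor for interferon-induced chemokines (-1.01), the integrin Itgal (-0.65) and Selplg (-0.59) lower. In these libraries neutrophil markers held 1.39% of counts in BMF and 4.72% in BAR, and erythroid markers stood at 8.40 and 555 CPM.

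T cell receptor signalling and CD8 identity genes fell at day 14: 0 of 27 rose and 21 fell (0 and 23 adjusted over the list alone), with a median log2 of -0.46 and a camera adjusted p of 4.75e-12 (adjusted p = 0.196 with an estimated correlation). Rasgrp1, which activates Ras below the receptor, fell from 142 ± 28.0 to 65.0 ± 9.26 CPM (log2 -1.13, SE 0.137, adjusted p = 4.11e-05), with Prkcq (-0.68). Cd8a was at 832 ± 131 CPM in BMF and 657 ± 59.3 CPM in BAR and did not pass (log2 -0.34, SE 0.134, adjusted p = 0.0694, and 0.0204 without BMF replicate 3). In the same libraries neutrophil markers held 1.39% of counts in BMF and 4.72% in BAR. With these as a covariate 0 members rose and 7 fell (median -0.32). Naive and memory markers had 8 rises and 10 falls of 32 (8 and 12 adjusted over the list alone, camera adjusted p = 0.282), among them Als2cl (-0.75), and Tcf7 had a log2 value of 0.27 (adjusted p = 0.401). Exhaustion and inhibitory receptors had 5 rises and 6 falls of 29 (6 and 6 adjusted over the list alone, camera adjusted p = 0.607): Cd200 (0.80) and Nt5e (1.06) rose, Ptger4 fell (-0.93), and Pdcd1 had a log2 value of -0.11 (adjusted p = 0.572).

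Camera called mitosis genes lower at day 14. In that list 0 of 58 rose and 29 fell (0 and 32 adjusted over the list alone, median log2 -0.31, camera adjusted p = 6.24e-09, and adjusted p = 0.311 with an estimated correlation). Cdc25b, a phosphatase of entry into mitosis, fell from 87.4 ± 8.89 to 47.7 ± 1.34 CPM (log2 -0.87, SE 0.117, adjusted p = 8.01e-05), with Kif4 (-0.67) and Racgap1 (-0.58). Mki67 fell by 0.50 (SE 0.165, adjusted p = 0.0334), a call lost without any of 4 of the 6 libraries (adjusted p of up to 0.192 without BMF replicate 2). With the neutrophil covariate 6 mitosis genes fell and 0 rose (median -0.23). DNA replication genes had 3 rises and 4 falls of 50, also adjusted over the list alone (camera adjusted p = 0.213), with Ticrr (-0.80) and Pole (-0.66) lower and Ccne1 (0.53) higher.

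**Figure D4:**
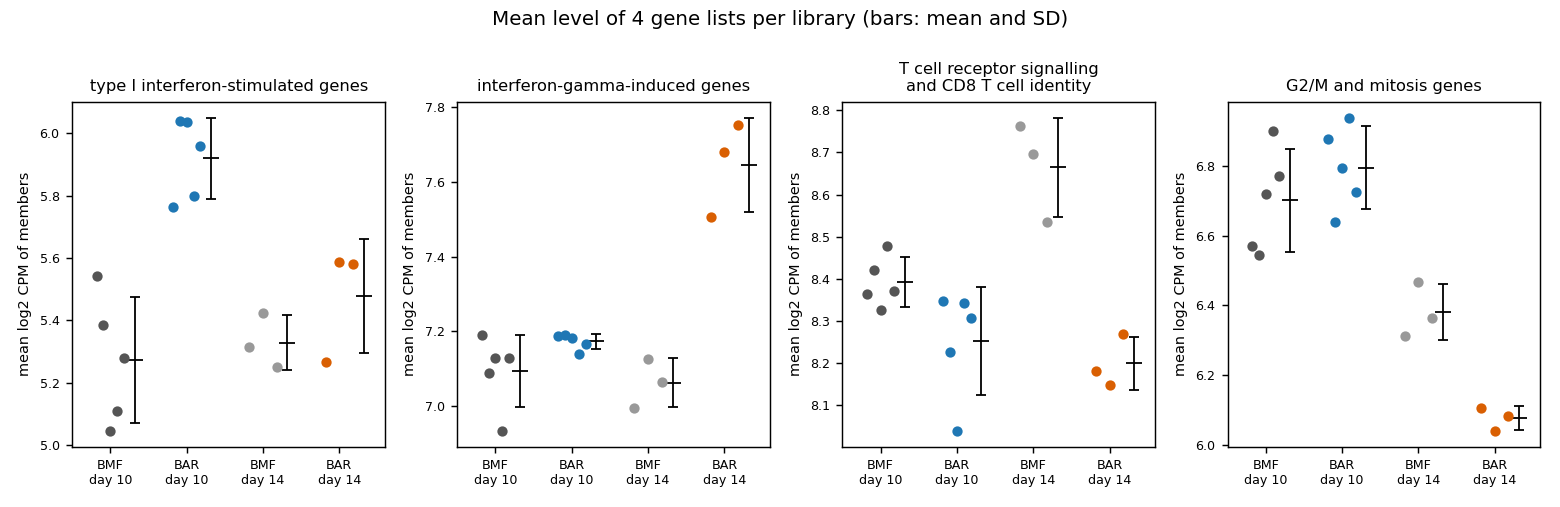
Mean log2 CPM of the members of 4 functional lists in each of the 16 libraries (points), with mean and SD per group. Type I interferon-stimulated genes separate the arms at day 10, and interferon-gamma-induced, T cell receptor and mitosis genes separate them at day 14.

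In the cholesterol, glycolysis, MYC and stress response lists more genes rose than fell at day 14, though most members did not pass. In the same libraries neutrophil markers held 1.39% of counts in BMF and 4.72% in BAR, and erythroid markers stood at 8.40 and 555 CPM. Cholesterol biosynthesis had 11 rises and 0 falls of 26 (12 and 0 adjusted over the list alone, median log2 0.25, camera adjusted p = 0.000733, and adjusted p = 0.260 with an estimated correlation). Fdps, which makes farnesyl diphosphate, rose from 44.4 ± 7.05 to 123 ± 20.6 CPM (log2 1.47, SE 0.166, adjusted p = 3.10e-05), with Sqle (1.10) and Msmo1 (0.91). Glycolysis had 10 rises and 2 falls of 26 (13 and 2 adjusted over the list alone, median 0.36, or 0.18 with the neutrophil covariate, camera adjusted p = 0.00274, and adjusted p = 0.294 with an estimated correlation), among them Pfkm (1.03), the lactate transporter Slc16a1 (0.74) and Hk2 (0.64). MYC and ribosome biogenesis had 13 rises and 1 fall of 43 (15 and 1 adjusted over the list alone, median 0.17, or 0.34 with the neutrophil covariate, camera adjusted p = 0.00154, and adjusted p = 0.444 with an estimated correlation), with Ifrd2 (1.18), Wdr12 (0.76) and Srm (0.83). The unfolded protein and amino acid stress response had 6 rises and 1 fall of 35 (5 and 1 adjusted over the list alone, median 0.23, or 0.13 among genes of at least 10 CPM, camera adjusted p = 0.0218, and adjusted p = 0.262 with an estimated correlation; adjusted p = 0.0642 without BAR replicate 3). Asns, asparagine synthetase, rose from 29.1 ± 4.29 to 74.6 ± 10.8 CPM (log2 1.36, SE 0.168, adjusted p = 5.33e-05), Xbp1 rose (0.50) and Ddit4 fell (-0.77). Oxidative phosphorylation had 5 rises and 2 falls of 59 (3 and 0 adjusted over the list alone, camera adjusted p = 0.715). Cycs (0.58), Cyc1 (0.46) and Atp5g1 (0.33) were among the rises; Cyc1 had an adjusted p of 0.0789 without BAR replicate 2 and Atp5g1 of 0.0581 without BMF replicate 2.

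Apoptosis regulators and p53 targets had 3 rises and 9 falls of 38 at day 14, also adjusted over the list alone (median log2 -0.15, camera adjusted p = 0.0147, and adjusted p = 0.111 with an estimated correlation; median -0.08 and adjusted p = 0.324 among genes of at least 10 CPM). Bbc3 (-0.76) and Bcl2 fell, which act in opposite ways on cell death, and Tnfrsf1a rose (0.76). Immediate early and dissociation stress genes had 6 rises and 1 fall of 33, also adjusted over the list alone (median 0.36, camera adjusted p = 0.00321, and adjusted p = 0.444 with an estimated correlation). Fosl2 (0.95) and Egr2 (0.57) rose. Hspa1a, an inducible heat shock protein with the near-identical copy Hspa1b, was at 0.525 ± 0.517 CPM in BMF and 17.3 ± 4.96 CPM in BAR (log2 5.03, SE 1.24, adjusted p = 0.0113; 0.0550 without BMF replicate 1).

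Whether the effect of baricitinib differed between the days was tested directly. Hspa1a and the erythroid genes Aqp1 and Rhag had a more positive effect at day 14, while Ccdc80, Gzma and Ifi27l2a had a more negative one. The difference was called by edgeR for 1535 genes, 743 with a more positive and 792 with a more negative effect at day 14. Among the largest were Hspa1a (log2 difference 6.51, SE 1.44, adjusted p = 0.0157; 0.0563 without BMF day 14 replicate 1), Sphk1 (6.02), Aqp1 (5.70) and Rhag (5.59). At the other end were Ccdc80 (-3.59), Gzma (-2.76, SE 0.322, adjusted p = 0.000526), Fabp4 (-2.46), Ifi27l2a, an interferon-stimulated gene (-2.08, SE 0.252, adjusted p = 0.000481), and Apoe (-1.95). The count was 679, 846 and 827 without day 14 libraries BMF replicate 2, BMF replicate 1 or BAR replicate 2, 2025 without BMF day 10 replicate 5, and 413 without the libraries richest in Rn45s, where 58.8% were more positive against 48.4%. It was 3284 with limma voom, 160 against a fold of 1.5 and 1013 with the neutrophil covariate.

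By list, camera called 8 differences between the days, and 0 with an estimated correlation. Of 100 regroupings of the libraries, the real one included, 44 gave at least 8 lists. Erythroid markers were at 167 CPM in BAR and 53.01 CPM in BMF at day 10, and at 555 and 8.40 CPM at day 14. Neutrophil markers were at 10004 and 6352 CPM at day 10, and at 47182 and 13918 CPM at day 14. For type I interferon-stimulated genes the effect was lower at day 14. Of 44 members 0 had a more positive and 18 a more negative effect, with 0 and 23 adjusted over the list alone (median log2 difference -0.48, adjusted p = 1.91e-13, and adjusted p = 0.275 with an estimated correlation). Mitosis genes had 0 and 24 of 58, with 0 and 30 adjusted over the list alone (median log2 difference -0.38, or -0.23 without the libraries richest in Rn45s, adjusted p = 2.71e-15, and adjusted p = 0.3002 with an estimated correlation). T cell receptor and CD8 identity genes had 0 and 6 of 27, with 0 and 9 adjusted over the list alone (median log2 difference -0.32, adjusted p = 4.36e-07, and adjusted p = 0.3002 with an estimated correlation). DNA replication genes had 0 and 6 of 50, with 1 and 6 adjusted over the list alone (median log2 difference -0.19, or -0.12 with 1 surrogate variable, adjusted p = 0.000137, and adjusted p = 0.633 with an estimated correlation). The effect was higher at day 14 for the other called lists. Interferon-gamma-induced genes had 12 and 1 of 38, with 20 and 2 adjusted over the list alone (median log2 difference 0.44, adjusted p = 1.56e-07, and adjusted p = 0.275 with an estimated correlation). Glycolysis had 10 and 0 of 26, with 14 and 1 adjusted over the list alone (median log2 difference 0.46, adjusted p = 1.43e-06, and adjusted p = 0.275 with an estimated correlation). Immediate early and stress genes had 6 and 0 of 33, with 9 and 0 adjusted over the list alone (median log2 difference 1.001, or 0.48 without the libraries richest in Rn45s, adjusted p = 6.31e-07, and adjusted p = 0.3002 with an estimated correlation). MYC and ribosome biogenesis genes had 5 and 0 of 43, with 5 and 0 adjusted over the list alone (median log2 difference 0.12, from 0.06 with limma voom to 0.22 with the neutrophil covariate, adjusted p = 0.0138, and adjusted p = 0.698 with an estimated correlation). The MYC call was lost without BAR day 10 replicate 2 (adjusted p = 0.156) or BMF day 14 replicate 3 (0.0680). The cytotoxic list had 1 more positive and 8 more negative effects of 30, a median of 0.03, a mean of -0.06 and a camera adjusted p of 0.303. The other lists had camera adjusted p between 0.0765 and 0.924.

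Across genes, the effects of both days were related. The fold changes had a Spearman rho of 0.338 over 14862 genes and 61.2% had the same sign; among the 2145 genes called at day 10 rho was 0.573 and 76.6% had the same sign. Genes are not independent replicates, and the comparisons shared no libraries. Rises at both days were found for 325 genes (125 by the product of the list lengths; Fisher's exact p = 2.90e-67) and falls at both for 329 (144; p = 1.54e-52). Il12rb2, Ifngr1, Bbc3, Ahnak, Serpinb9 and Serpinb6b fell at both days, and Isg20, Cd200, Nt5e, Sqle, Fdps, Srm and Ifrd2 rose at both. Opposite calls were fewer than that product. By Fisher's exact test, 64 genes were higher at day 10 and lower at day 14 (118, p = 5.57e-09) and 20 the reverse (153, p = 2.29e-47). Cd200r1 was one of the former and Hk2 one of the latter.

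Without drug, day 14 was compared with day 10 by 3 and 5 BMF libraries. Adgrg1, an adhesion receptor of cytotoxic lymphocytes, rose from 46.0 ± 4.21 to 182 ± 24.0 CPM (log2 1.98, SE 0.107, adjusted p = 4.10e-09). Immediate early and dissociation stress genes had 1 rise and 16 falls of 33, also adjusted over the list alone (median log2 -0.88, camera adjusted p = 0.000129, and adjusted p = 0.497 with an estimated correlation). Among them Hspa1a (log2 -5.99, SE 1.23, adjusted p = 0.00265) and Hspa1b (-5.38) fell from means of 33.7 ± 30.5 and 79.1 ± 65.4 CPM at day 10. Gsta4 (2.40), Glp1r (2.25), Trf, transferrin (2.08), and Slc40a1, the iron exporter ferroportin (1.99), rose too. Fos (-3.91; adjusted p of up to 0.0680 without BMF day 14 replicate 1), Car1 (-3.13) and Mcpt8, a basophil protease (-2.95), fell. EdgeR called 5728 genes, 2623 higher and 3105 lower at day 14. Mitosis genes had 1 rise and 35 falls of 58 (1 and 39 adjusted over the list alone, camera adjusted p = 1.43e-07, and adjusted p = 0.497 with an estimated correlation). T cell receptor genes had 16 rises and 0 falls of 27, also adjusted over the list alone (adjusted p = 5.75e-05, and adjusted p = 0.497 with an estimated correlation). DNA replication genes had 1 rise and 26 falls of 50 (2 and 27 adjusted over the list alone, adjusted p = 5.75e-05, and adjusted p = 0.531 with an estimated correlation). MYC and ribosome biogenesis genes had 3 rises and 23 falls of 43 (3 and 26 adjusted over the list alone, adjusted p = 7.11e-05, and adjusted p = 0.497 with an estimated correlation). The exhaustion, homing and apoptosis lists were called higher too, with adjusted p of 0.0289, 0.0335 and 0.0360 (0.497, 0.497 and 0.192 with an estimated correlation). In the same libraries erythroid markers were at 53.01 CPM at day 10 and 8.40 CPM at day 14, neutrophil markers at 6352 and 13918 CPM, and mast cell, basophil and eosinophil markers at 110 and 21.3 CPM. JAK-STAT components had 16 rises and 3 falls of 37 (17 and 3 adjusted over the list alone, adjusted p = 0.000578, and adjusted p = 0.0175 with an estimated correlation). The count of genes was 2459 without the libraries richest in Rn45s, 3792 among genes of at least 10 CPM and 846 (20.3% rises, against 45.8%) against a fold of 1.5.

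With baricitinib, day 14 was compared with day 10 by 3 and 5 BAR libraries. Mitosis genes were lower almost throughout, with 1 rise and 56 falls of 58, also adjusted over the list alone (median log2 -0.73, camera adjusted p = 4.96e-38, and adjusted p = 0.162 with an estimated correlation). DNA replication genes had 0 rises and 40 falls of 50 (0 and 43 adjusted over the list alone, adjusted p = 5.70e-15, and adjusted p = 0.243 with an estimated correlation). Among the largest falls were the B cell genes Vpreb3 (log2 -6.47), Cd79a (-5.02), Fcrla (-4.87) and Spib (-4.84), which BAR day 10 replicate 3 carried at high levels. The largest rises by the same limits were Scnn1a (3.20), Mogat2 (2.96), Fcnb, a ficolin of neutrophil precursors (2.96, SE 0.746, adjusted p = 0.00852), Tmcc2 (2.95) and Cebpe, a transcription factor of granulocytes (2.85). Type I interferon-stimulated genes had 4 rises and 22 falls of 44 (5 and 22 adjusted over the list alone, adjusted p = 6.66e-07, and adjusted p = 0.328 with an estimated correlation). Interferon-gamma-induced genes had 20 rises and 2 falls of 38 (21 and 2 adjusted over the list alone, adjusted p = 1.85e-07, and adjusted p = 0.162 with an estimated correlation). Glycolysis had 14 rises and 1 fall of 26 (16 and 1 adjusted over the list alone, adjusted p = 8.50e-05, and adjusted p = 0.257 with an estimated correlation). Cholesterol biosynthesis had 9 rises and 1 fall of 26, also adjusted over the list alone (adjusted p = 0.0133, and adjusted p = 0.487 with an estimated correlation). Neutrophil markers stood at 47182 CPM at day 14 and 10004 CPM at day 10, and erythroid markers at 555 and 167 CPM. EdgeR called 5808 genes, 2859 higher and 2949 lower at day 14, with 3842 without BAR day 14 replicate 2, 3868 among genes of at least 10 CPM, 896 against a fold of 1.5 and 1981 with the neutrophil covariate, where 141 of the 5808 genes had the opposite sign. In either arm, day and any batch of harvest or library making are the same split of the libraries and cannot be separated.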

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

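Chosen after the results were seen were the test of depth at day 14, camera with the neutrophil covariate at day 14, and the comparisons of the T cell receptor list with the exhaustion list and of the mitosis list with the replication list.

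In 290 groups of 5 libraries, 30 had a library far from the others by Dixon's test. For independent groups of normally distributed values chance gives 1 in 20. Most values here were CPM on their own scale, and many flagged groups share a library, so 1 in 20 is no measure of chance for them. In BAR day 10 replicate 3, B cell genes stood high: Cd79a was at 78.2 CPM (3.59 to 12.2 in the other BAR libraries), Fcrla at 36.5 (2.17 to 6.05), Vpreb3 at 85.2 (2.73 to 12.4), Mzb1 at 33.3 (3.25 to 9.31) and Spib at 82.9 (5.27 to 13.9). The same library held 61.2 CPM of Ly6d (10.9 to 21.1), 51.0 of Atp1b1 (6.77 to 12.8) and 25.9 of Cox6a2 (4.19 to 9.38), with sums of 641 CPM for B cell markers (48.8 to 112) and 4886 CPM for dendritic cell markers (943 to 1160). It was low in Ermn (1.02 CPM against 3.05 to 3.33), Serpinb9b (0.627 against 1.34 to 1.53) and Stat4 (153 against 194 to 203). BMF day 10 replicate 5 had 269 CPM of Ahnak (433 to 448 in the other BMF libraries), 98.9 of Cd44 (124 to 134), 135 of Cyc1 (106 to 109), 72.6 of Fcnb (9.82 to 25.98) and 8.93 of Trf (4.69 to 5.87). BAR day 10 replicate 2 had 93.3 CPM of Fos (6.17 to 26.6), 32.3 of Hspa1a (5.24 to 10.6), 65.1 of Hspa1b (14.9 to 24.6), 211 of Gzma (304 to 335) and 12.7 of Ldhb (9.80 to 10.4). Single values apart from their groups were Cd200 at 71.9 CPM in BAR day 10 replicate 1 (74.1 to 74.9), Cox6a2 at 2.82 in BMF day 10 replicate 1 (0.162 to 0.828), Epas1 at 39.8 (22.9 to 26.8) and Gzmc at 22.6 (4.69 to 8.48) in replicate 3, and Gbp6 at 89.1 in replicate 4 (101 to 106).

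The baricitinib effect differed between the days, by edgeR's test of the difference, for 69 of 136 genes chosen by the naming rule. That rule took genes with large changes, some of them by this same test, so the choice itself raises the share. Among all 14862 genes tested, 1535 (10.3%) differed. Values of the named genes reported here are the log2 effect at day 14 minus that at day 10. Differences above 0 began with Hspa1a 6.51, Sphk1 6.02, Aqp1 5.70, Rhag 5.59, Abcb4 5.26, Cldn13 5.22, Ermap 5.15, Slc38a5 5.09, Ermn 2.25 and Epas1 1.90. Next in size were Gbp2 1.75, Serpinb9b 1.75, AA467197 1.53, Ier5 1.52, Atf4 1.51, Hsp90aa1 1.39, Hk2 1.28, Satb1 1.25, Fosl2 1.11, Slc16a1 1.10, Egr3 1.09 and Asns 1.06. Smaller positive differences were Fdps 1.04, Pfkm 1.01, Il12rb2 0.99, Irgm2 0.96, Cd44 0.95, Ifrd2 0.85, Bhlhe40 0.73, Sqle 0.67, Irgm1 0.65, Wdr12 0.62, Tnfrsf1a 0.60 and Il18rap 0.60. The smallest positive ones were Nop14 0.52 and Slc2a1 0.52. Differences below 0 began with Ccdc80 -3.59, Gzma -2.76, Fabp4 -2.46, Ifi27l2a -2.08, Apoe -1.95, Cd7 -1.57, Cd200r1 -1.53, Vax2 -1.35, Prr5 -1.33, Dhx58 -1.11, Gbp10 -1.03 and Phf11b -1.03. Then came Ptger4 -0.99, Pim2 -0.97, Cdc25b -0.87, Rasgrp1 -0.86, D8Ertd82e -0.84, Cxcr3 -0.83, Ticrr -0.81, Kif4 -0.80, Pole -0.73, Fasl -0.69, Runx3 -0.65 and Kif20a -0.65. Smaller negative differences were Usp18 -0.62, Cenpm -0.59, Pold1 -0.58, Selplg -0.58, Racgap1 -0.56 and Ifnar1 -0.50. Among lists, camera found median differences of -0.48 for type I interferon-stimulated genes, 0.44 for interferon-gamma-induced genes, -0.32 for T cell receptor signalling and CD8 identity, -0.19 for DNA replication, -0.38 for mitosis, 0.46 for glycolysis, 0.12 for MYC and ribosome biogenesis and 1.001 for immediate early and stress genes; 0 of these held with an estimated correlation.

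Erythroid genes were higher with baricitinib at day 14 (13 of 13 called by edgeR), although the cells had been flow-sorted for CD8. Summed neutrophil and monocyte markers had higher means without overlap of the arms (exact p = 0.1 each, the smallest this design gives), but 0 of 21 neutrophil genes were called and monocyte genes had 7 rises and 7 falls. The 21 abundant neutrophil genes moved together over the 16 libraries, with a median pairwise correlation of 0.932 (0.983 within day 14 and 0.852 within day 10), which is consistent with RNA or cells of that type in the sorted samples. Their most abundant genes were Ngp at 15677 CPM in BAR and 3762 in BMF and S100a8 at 11990 and 4600 CPM, Lyz2 of monocytes was at 3611 and 802 CPM, and no gene of the neutrophil list is in another list. Mean depth differed by a ratio of 1.02 between the arms, which argues against depth. The treatment, which the design names, stays open and untested, as does a difference in the purity of the sorts, because each arm was measured without a stated batch.

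T cell receptor, CD8 identity and mitosis genes were lower with baricitinib at day 14. With the neutrophil list as a covariate the medians were -0.32 (bootstrap SE 0.0404; -0.46 without it) and -0.23 (SE 0.0340; -0.31 without it), and falls dropped from 21 to 7 and from 29 to 6 as the standard errors grew. Camera at the preset correlation still called both lists lower with it, with adjusted p of 1.27e-09 and 3.20e-07 (4.22e-14 to 1.27e-09 and 2.64e-12 to 4.37e-07 over 11 fits). Without the covariate neither list passed with an estimated correlation (adjusted p = 0.196 and 0.311). The kept calls say little about neutrophil RNA as the whole cause. In other splits of the day 14 libraries, camera at the preset correlation called up to 11 lists, against 13 in the real one. Whether neutrophil RNA was the whole cause therefore stays open. For dilution by any other cells, both medians lay past the bounds set beforehand by less than their SE. Bootstrap SEs here and below came from drawing the members of a list again 10000 times. Libraries were not drawn again, so these SEs leave out the spread between libraries. The exhaustion list lay above the T cell receptor list by 0.38 (SE 0.0977) and the replication list above the mitosis list by 0.28 (SE 0.0509), where dilution alone would lower them alike. Both gaps exceeded a bound of 0.2, but by less than the 2 SE asked for, so they do not settle whether dilution alone acted. The covariate follows neutrophils, and RNA of other cells that carry exhaustion or replication genes could lift those lists. A part played by dilution and a change within T cells therefore cannot be told apart.

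Type I interferon-stimulated genes were higher with baricitinib at day 10. With Rn45s as a covariate the median was 0.62 (bootstrap SE 0.0808; 0.53 without it), 8 members passed against 30, and camera at the preset correlation still called the list (adjusted p = 1.7e-41; without a covariate 0.0188 with an estimated correlation). With the neutrophil covariate it was 0.51 (SE 0.0809), 31 members passed and camera's adjusted p was 4.96e-37. The median with Rn45s argues against the ribosomal RNA carried in the libraries as the whole cause. Neutrophil markers did not differ beyond their spread at day 10 (exact permutation p = 0.183), so the neutrophil covariate could change little. B cell and erythroid markers, which were higher in BAR, were not tried as covariates. The treatment, which the design names, RNA of other cells and an unrecorded batch stay open and were not tested.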

How the results depend on the processing

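Chosen after the data were seen were the fits with Rn45s or the neutrophil list as a covariate, those without the libraries richest in Rn45s, and those keeping 2 of 5 libraries. Of 4042 alternatives for 196 results of named genes, 3673 kept direction and side of the threshold, 322 no longer passed, 18 newly passed, 0 reversed (named genes only), and 29 values that had not passed changed sign; 60 results were the same in every alternative run. Calls were lost most often against a fold of 1.5 (110), with the Rn45s covariate (55), without the Rn45s-rich libraries (49) and with the neutrophil covariate (24).

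At day 10, 2145 genes became 3611 with limma voom, 38 against a fold of 1.5, 66 with the Rn45s covariate, 1356 with the neutrophil covariate, 111 without the Rn45s-rich libraries and a median of 1354 with 2 of the 5 BMF libraries kept (109 to 146 with replicate 5 among them, 1234 to 2825 without it); leaving out 1 library gave 1036 (BMF replicate 3) to 3615 (BMF replicate 5). At day 14, 3738 became 5919 with limma voom, 556 against a fold of 1.5 and 993 with the neutrophil covariate; leaving out 1 library gave 2119 (BMF replicate 2) to 3774 (BMF replicate 3). The difference between days, 1535 genes, became 3284 with limma voom, 160 against a fold of 1.5 (68.8% more positive, against 48.4%), 1013 with the neutrophil covariate and 413 without the Rn45s-rich libraries, and 679 (BMF day 14 replicate 2) to 2025 (BMF day 10 replicate 5) without 1 library. Day 14 against day 10 in BMF, 5728 genes, became 3792 at 10 CPM or more, where fewer genes were tested, 846 against a fold of 1.5, 2459 without the Rn45s-rich libraries, and 4348 to 6241 without 1 library. In BAR, 5808 genes became 3868, 896 and, with the neutrophil covariate, 1981, and 3842 (BAR day 14 replicate 2) to 5624 without 1 library.

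The correlation of the effects of both days, 0.338, was 0.573 among genes called at day 10, and 0.279 to 0.403 without 1 library. With an estimated correlation camera called 4 of 13 lists at day 10, 0 of 13 at day 14 and 0 of 8 between days. Fry called 7, 14 and 7 of the 19 lists, not always the same ones. Without 1 library, camera at the preset correlation called 10 to 16, 12 to 13 and 8 to 9 lists, against 13, 13 and 8 with all libraries. By mean log2 CPM 0 marker lists passed at day 10, against 7 by summed CPM. B cell markers kept the smallest exact permutation p possible (0.00794, adjusted p = 0.0774), which cannot pass alone over 13 lists. Apart from fewer genes or libraries tested, the cause was not tested.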

Other observations

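The comparisons with other splits of the libraries were planned. Dividing the regroupings between days by their day 14 arms was not part of the rule written beforehand. The marker genes named here were chosen after their values were seen.

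Genes of basophils, eosinophils and blood progenitors stood higher in BAR at day 14. Prss34, a basophil protease, was at 8.88 CPM in BMF and 291 CPM in BAR (log2 5.02, edgeR adjusted p = 0.00621), Mcpt8 at 3.34 and 68.0 CPM, and Prg2, an eosinophil granule protein, at 0.807 and 38.2 CPM. Among progenitor genes Lmo2 was at 11.3 and 75.4 CPM (log2 2.73) and Tal1 at 0.262 and 13.3 CPM, while Ly6a, which activated T cells also express, fell from 372 to 201 CPM. Folds of genes below 1 CPM in BMF rest on few counts. Of the natural killer list, Klra3 (log2 -0.94), Txk (-0.60), Eomes (-0.39) and Gzma (-2.61) fell and Fcer1g rose (1.66).

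Other splits of the libraries bear on the counts. At day 10, 1 of 100 splits, the real one, gave as many as 2145 genes, and the highest other gave 856. The splits that exchanged only BMF replicate 5 and a BAR library gave 755 to 856 genes, and the remaining mixed ones 0 or 1. That BMF library was close to the BAR means in its share of Rn45s (1.15%, BAR mean 1.30%) and Lars2 (0.848%, BAR mean 0.748%). Splits that mix the arms put any real difference into the spread between replicates, which limits how many genes can pass in them. A share of 1 in 100 is small but does not exclude chance. Libraries of a group may be repeats of pooled cells, and then the splits say nothing about animals. The same holds for day 14 against day 10, with 1 of 56 splits in BMF (5728 genes, highest other 2075) and 1 of 56 in BAR (5808, highest other 576). At day 14 the 10 splits are too few for a share under 0.05 (3738 genes, highest other 1). For the difference between days, the rule written beforehand was that a share of 0.05 or more goes with chance. Of 100 regroupings, 7 gave at least 1535 genes, with up to 4452, so by that rule chance was not excluded. The 6 besides the real one kept the day 14 arms whole or exchanged them and so still held the day 14 effect. These regroupings therefore cannot decide the question. The 88 that mixed the day 14 arms, and so put that effect into the spread between replicates, gave up to 26. For lists, 5 of 100 splits gave at least 13 at day 10 (highest other 15) and 44 of 100 at least 8 between days (highest other 14), 32 of them with the day 14 arms mixed, so chance cannot be excluded; at day 14 the splits are too few (1 of 10; 13 lists, highest other 11).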
